A study of Halobacterium salinarum NRC-1 with 22 samples.

How the data were processed

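RNA of the archaeon Halobacterium salinarum NRC-1, an extreme halophile, was measured on 22 arrays of 2 colours. Mid-log cultures received 6.0 mM FeSO4, and RNA was taken at 11 times: -1, 0, 5, 10, 15, 20, 25, 40, 80, 160 and 320 minutes. Each RNA was hybridised on 2 arrays against a standard control RNA, with the dyes Alexa 532 and Alexa 647 exchanged between the arrays, per the labels. The 2 arrays of a time point hold the same 2 RNAs and were counted as 1 sample, so each time point had 1 sample. Nothing in the labels says that the time points came from separate cultures, so p-values measure only the spread between these RNAs, which may be technical.

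The values are log ratios of the 2 channels per spot, as deposited by the authors. Their log base, scanner, background correction, normalization and filters are not given in the sources used here. The base was not recovered from the values either, so all differences are in deposited log units. If the base was 10, a 2-fold difference is 0.30 units, and if it was 2, it is 1 unit. The scale and the centring stay unknown. The direction of the ratios was taken as Alexa 532 over Alexa 647, in the word order of the labels' descriptions. It is therefore called likely. Arrays of 1 dye orientation correlated positively with each other over features (r from 0.26 to 0.91 for Alexa 532, and from 0.11 to 0.88 for Alexa 647).

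In the deposited columns with the FeSO4 RNA in Alexa 532, the medians from -1 to 320 minutes in time order were 0, 0.058, 0.106, 0.077, 0.065, 0.069, 0.066, 0.112, 0.069, 0.102 and 0.088. In those with the FeSO4 RNA in Alexa 647 they were 0, 0.11, 0.076, 0.0036, 0.034, 0.0034, 0.052, 0.020, 0.022, 0.098 and 0.065. The table held 10752 spots. An exact 0 was repeated on most arrays, at up to 24.9% of the spots (median 1.33%), while no other value occurred more than 2 times on an array. Exact 0 was therefore treated as no measurement. The most affected arrays were those of -1 minute.

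A platform annotation table paired 532 spots with 1 gene symbol each and none with several. The other 10220 spots are unnamed here. The named spots stood for 133 genes, and all 133 had 4 spots in 1 layout of 2 neighbouring spots in each of 2 printed copies. The same layout was assumed for the unnamed spots, which gave 2688 features, of which 2555 are unnamed. Neighbouring spots of a feature correlated at a median r of 0.880 over features, and neighbouring spots of different features at 0.338. The 2 printed copies correlated at a median of 0.615, and between -0.111 and 0.837 on single arrays. The lowest values were those of the -1 minute arrays (0.137 and -0.111) and of the Alexa 647 arrays of 20 minutes (0.072) and 40 minutes (0.053). An annotation of another strain of the species was looked through by gene identifier, with 0 matches, so no coordinates are given. No intensities were used, and the number of arrays limits the precision.

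The spots of a feature were averaged, and the sign of the arrays with the FeSO4 RNA in Alexa 647 was turned. The 2 arrays of an RNA were then averaged, which cancels a constant dye effect but not one that varies between arrays. The turned ratios correlated over features with the mean of all arrays before turning. The r ran from -0.243 at 25 minutes to 0.365 at 20, 0.526 at 80 and 0.731 at 40 minutes. Turning assumes that the authors had deposited every ratio in 1 dye order, which the word order of the labels implies and nothing states. The values leave some doubt. The mean of the 2 orientations before turning correlated at a median r of 0.853 between times from 0 minutes on, which a dye effect or a difference of every RNA from the control would both give. The -1 minute RNA, 1 of the 2 baseline RNAs, stood apart here, at r from 0.302 to 0.427 with the other times. After the data were seen, each orientation's deviations from its mean over time were therefore compared between the 2 arrays of an RNA. They correlated negatively over features at 8 of the 11 times, as ratios not yet turned would, and positively at -1, 160 and 320 minutes (r from -0.600 to 0.626). The error of a single time point is given as the deviation of its 2 printed copies from their mean, or by both orientations side by side. Both are technical.

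Choices made before the data were examined were as follows. RNAs were grouped as baseline (-1 and 0 minutes, n = 2), early (5 to 25 minutes, n = 5) and late (40 to 320 minutes, n = 4). The 3 contrasts were fitted in 1 model over the 11 RNAs with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided). A slope on log2 minutes was fitted over the 9 RNAs after the addition. The Benjamini-Hochberg adjusted p had to be below 0.05. Of 20 gene lists, 9 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over all 27 tests. The lists of siderophore and iron uptake, transcription machinery, ATP synthase, gas vesicle and transposase genes had no member among the named genes, and 6 lists had 1 or 2 members and were not tested as lists.

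Genes were named by a rule. For each phase contrast, it took the 10 largest rises and falls among genes past the threshold with the same sign in both dye orientations, or, where no named gene passed, the 5 smallest p in each direction as values only. For the slope it took 5 in each direction in the same way. It added 4 members with the smallest p from each list in each contrast discussed, the metal list, and a set of iron and stress genes of which dpsA alone was among the named genes. The rule was narrowed after the values and the alternatives had been seen. Members were named one by one only for lists that camera called in that contrast and, for late against early, for lists of 1 or 2 members. The whole rule would have named 134 gene and contrast pairs, of which 70 are left out here, and their changes of sign are counted in the closing section. Unnamed features are given by the number of their first spot.

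The arrays carry numbers in the labels. Those of 5, 10, 15 and 25 minutes form the upper stretch of numbers (7120 to 7131). Those of the other 7 times form the lower one (7084 to 7115). The border was drawn here, and no label names it. The gap there was no wider than that from 7123 to 7128, and narrower than that from 7088 to 7101 in the lower stretch. Below that wider gap lie the arrays of -1 minute and the Alexa 532 array of 0 minutes. The stretch of numbers is called the array run. It was tested as a block because it holds 4 of the 5 early RNAs and the 20 minute RNA is the only early one in the other run. The alternatives fixed beforehand covered single dye orientations, a model of all 22 arrays, centring, scale and quantile normalization, spot medians, filters, the variance prior, the array number, other phase borders and each RNA left out in turn. Others were added after seeing the data: exact 0 kept, ratios left unturned, the array run as a block (for the lists also with an estimated correlation), the 4 RNAs of the upper run left out, and adjustment of each RNA for the mean dye component by regression.

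The fits were tested on simulated data with the spread of these arrays. In each of 2 simulations, for the phases and for the slope, 200 of 2688 features were changed. The phase simulation also had the layout and missing spots of the arrays, while the slope and the lists were simulated per RNA. The noise was independent between features and between RNAs. It held no array run, so the rates below do not carry over to calls that follow the run. Differences of 0.1, 0.2 and 0.3 between early and baseline were recovered in 18%, 78% and 96% of features. Between late and early they were recovered in 40%, 86% and 100%. Of the unchanged features, 11 were called between early and baseline and 5 between late and early, and for the slope 9. Slopes of 0.05 per doubling of time were recovered in 88% of features. Of 100 simulated lists of 6 features without a shift, camera gave an unadjusted p below 0.05 for 9.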

Results

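Transcript ratios to a common control RNA were measured in Halobacterium salinarum NRC-1 around the addition of 6.0 mM FeSO4, a source of ferrous iron. There were 11 RNAs, 1 per time point, each on 2 dye-swapped arrays. The baseline held 2 RNAs (-1 and 0 minutes), the early phase 5 (5 to 25 minutes) and the late phase 4 (40 to 320 minutes). Of 2688 features, 133 had gene names. The log base of the deposited ratios is not given in the sources used here, and values are in deposited log units. A positive value is likely a higher level in the FeSO4 RNA than in the control RNA, from the order of the words in the labels, and dye-swapped ratios were turned on that basis. The time points have no replicate RNA.

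The RNAs fell into 2 sets that matched the array run. One set held 4 of the 5 early RNAs, so it departed from the early phase by the 20 minute RNA alone. An early response shared by these 4 RNAs cannot be told apart from the run. The 5, 10, 15 and 25 minute RNAs, on the upper array numbers, correlated with each other over features at r of 0.589 to 0.827. With the other 7 RNAs they correlated at -0.163 to 0.175. The 20 minute RNA, on the lower numbers, correlated at -0.055 to 0.097 with these 4 and at 0.305 to 0.742 with the RNAs of 40 to 320 minutes. Features are not independent replicates, and no p-value is attached. Of 130 named genes with a value on all arrays, 26 were higher in all of the 4 RNAs than in any of the other 7, and 2 were lower. For comparisons with the early phase, counts of calls, lists and the genes named outside the lists are also given with the array run as a block. That fit leaves the 20 minute RNA as the only early one and takes it to vary like the other groups. On the 20 minute array with the FeSO4 RNA in Alexa 647, the 2 printed copies correlated at only 0.072 over features.

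**Figure D1:**
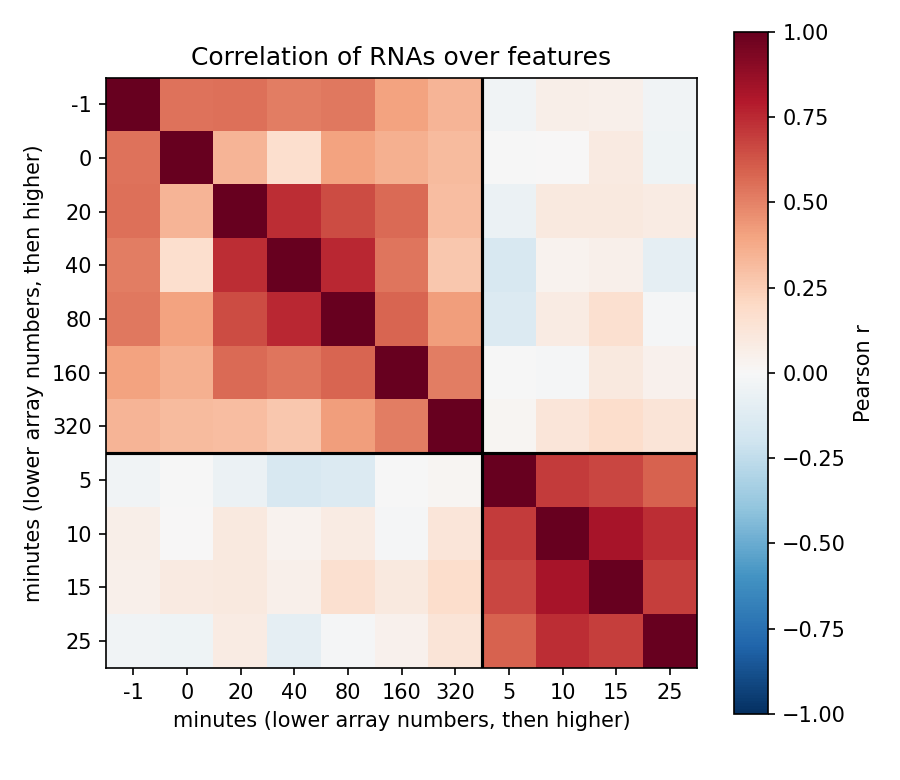
Pearson correlation over features between the log ratios of the 11 RNAs, with both axes in minutes and the RNAs of the lower array numbers placed before those of the upper ones. The 4 RNAs of the upper numbers correlate at 0.589 to 0.827 with each other and at -0.163 to 0.175 with the other 7.

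The time course of dpsA was looked at for the response to iron, because its product is a ferritin-like protein of the Dps family that stores iron and protects DNA. The dpsA ratio was -0.05 at -1 minute and -0.02 at 0 minutes. It was 0.05, 0.24, 0.23, 0.51 and 0.24 at 5, 10, 15, 20 and 25 minutes, and 0.27, 0.27, 0.17 and 0.06 at 40, 80, 160 and 320 minutes. The printed copies deviated from their mean by between 0.002 and 0.08 at these times. All 9 ratios after the addition lay above both baseline ratios, the 5 on the lower array numbers included, with means of 0.23 ± 0.14 (SD, n = 9) and -0.03 (n = 2). The exact permutation test gave a two-sided p of 0.0364, which is the smallest it can give for 9 against 2, and it treats the time points as exchangeable. At 20 minutes dpsA was 0.54 above the baseline mean, the largest such difference among 2606 features. If the base was 10 this is 3.48-fold, and if it was 2 it is 1.46-fold. In the separate orientations, the 20 minute dpsA ratio was 0.43 with the FeSO4 RNA in Alexa 532 and 0.59 in Alexa 647. The orientations stood further apart at 10 minutes, at -0.087 and 0.57. In Alexa 532 alone, 7 of the 9 later ratios lay above both baseline ratios. If the authors had already turned the ratios, dpsA would be at -0.080 at 20 minutes. In the fit over all features by limma, early dpsA exceeded the baseline by 0.29 ± 0.09 (SE), with an adjusted p of 0.178. With the array run as a block, which sets the 20 minute RNA alone against the baseline, the difference was 0.54 ± 0.09 (SE), with an adjusted p of 0.0467. That call was lost without the 4 upper-run RNAs, where the same dpsA difference had an adjusted p of 0.0710. Late dpsA exceeded the baseline by 0.22 ± 0.09 (SE), with an adjusted p of 0.599.

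**Figure D2:**
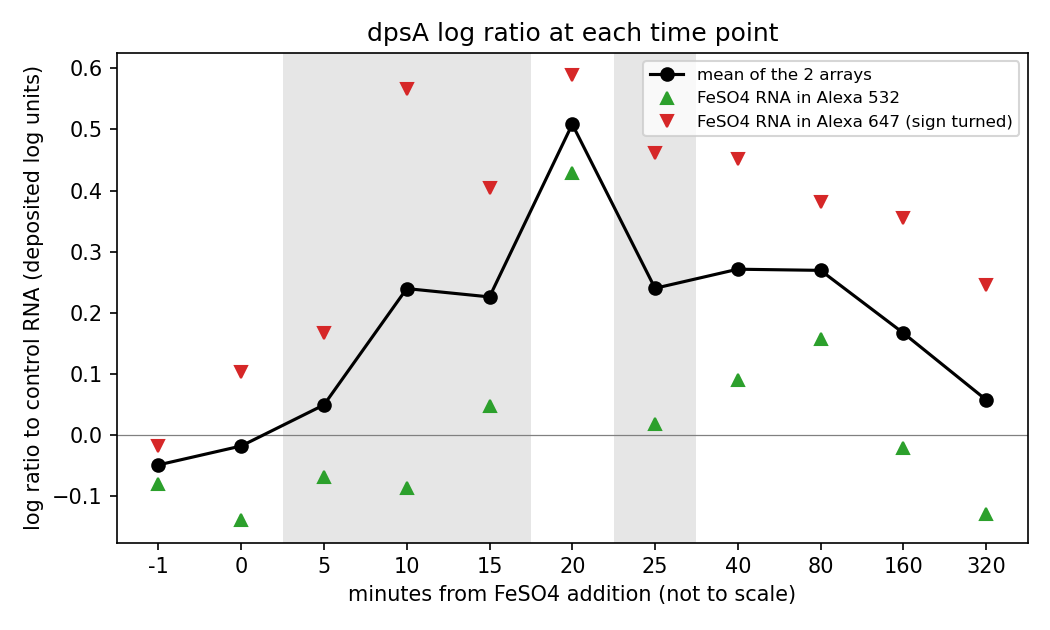
Log ratio of dpsA to the control RNA (vertical axis, deposited log units) at each time (horizontal axis, minutes, not to scale), with circles for the mean of the 2 arrays and triangles for each dye orientation. Grey marks the RNAs of the upper array numbers, and the mean reaches 0.51 at 20 minutes, where both orientations are high.

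Between early and baseline, no named gene passed the threshold in limma, 29 of 133 had an unadjusted p below 0.05, and the named genes are given as values. Among positive differences, the smallest p were those of guaB (IMP dehydrogenase of purine synthesis, 0.20 ± 0.05), rpmC (a ribosomal protein, 0.32 ± 0.08), eno (enolase, 0.20 ± 0.05), rimI (a ribosomal protein acetyltransferase, 0.14 ± 0.04) and thiD (thiamine synthesis, 0.27 ± 0.08), with SE in each case. Among negative differences, they were those of arcC (carbamate kinase of arginine fermentation, -0.17 ± 0.05), cheR (a chemotaxis methyltransferase, -0.12 ± 0.04), htr6 (a transducer, -0.066 ± 0.03), gdhB (glutamate dehydrogenase, -0.067 ± 0.03) and moaC (molybdenum cofactor synthesis, -0.052 ± 0.03). The choice was by p and not by size. The smallest adjusted p among named genes was 0.108, for guaB. The metal transport list had 1 measured member, cbiQ, a permease of cobalt uptake, at 0.087 ± 0.04. Blocked on the array run, the differences were 0.12 for guaB, 0.040 for rpmC, 0.083 for eno, 0.067 for rimI and -0.0012 for thiD. They were -0.012 for arcC, -0.027 for cheR, -0.068 for htr6, -0.076 for gdhB, -0.080 for moaC and 0.0034 for cbiQ, and none of these 11 passed.

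By camera, the chaperone and proteasome list was higher early than at baseline relative to the other features. All 6 members had positive differences, with 0 of 6 past the threshold over all features and 4 adjusted over the list alone. Its adjusted p was 0.00836, and the call was lost with an estimated correlation, at adjusted p = 0.479. Members with the smallest p were psmA (0.19) and psmB (0.135), the proteasome subunits, pan1 (0.099), and panB (0.079), a symbol used both for a proteasome-activating ATPase and for a pantothenate synthesis enzyme. The nucleotide synthesis list was higher as well, with 12 of 12 differences positive, 0 past the threshold and 1 adjusted over the list alone (guaB). Its adjusted p was 0.0320, and adjusted p = 0.498 with an estimated correlation. Besides guaB, pyrF was at 0.076, carA at 0.063 and purB at 0.053, and carA and purB differed in sign between the dye orientations. The chemotaxis list was lower, with 7 of 11 differences negative, none past the threshold over all features or adjusted over the list alone, and an adjusted p of 0.0179 that became an adjusted p of 0.479 with an estimated correlation. Besides cheR and htr6, cheA was at -0.048 and cheY at -0.038. The list of arginine fermentation and DMSO respiration was lower, with 3 of 3 differences negative, 0 past the threshold and 1 adjusted over the list alone. Its adjusted p was 0.0203, and adjusted p = 0.479 with an estimated correlation. Its members were arcC, arcA (arginine deiminase, -0.015) and moaA (molybdenum cofactor synthesis, -0.048). None of these 4 lists passed with the array run as a block, at adjusted p of 0.231, 0.836, 0.999 and 0.909 in this order, and relative to the other features the nucleotide list turned to lower, with 7 of 12 differences still positive, and the arginine and DMSO list to higher. The chaperone and proteasome list stayed higher with the block, with 5 of 6 differences positive. They were 0.218 ± 0.08 (SE) for psmA, 0.095 ± 0.07 for psmB, 0.117 ± 0.05 for pan1 and 0.088 ± 0.05 for panB. For the remaining members, dnaJ and dnaK, they were 0.012 and -0.015. The SE was larger than before (0.06 for psmA before), while the difference was smaller for psmB and turned negative for dnaK. The cobalamin list, not called before, was called lower with the block, at an adjusted p of 0.0167, and adjusted p = 0.427 with an estimated correlation, and also without the 4 upper-run RNAs (0.0154). The nucleotide call was lost without the -1, 5 or 15 minute RNA (adjusted p of 0.338, 0.115 and 0.0638). The chemotaxis call was lost without the -1 minute RNA (0.0642). With the dye component adjusted, camera lost the nucleotide call (adjusted p 0.0616) and the arginine and DMSO call (0.0789). It kept the chaperone and proteasome call (0.0155) and the chemotaxis call (0.0378).

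In all, limma called 5 of 2688 features between early and baseline, 3 higher and 2 lower, and none of them has a gene name here. The largest differences, chosen after the values were seen, were 0.33 ± 0.04 and 0.30 ± 0.05 (SE) for features 761 and 4329, and -0.24 ± 0.04 and -0.23 ± 0.04 for features 2341 and 2489. With each array centred on its median 24 features were called, 6 higher and 18 lower, and after quantile normalization 23, of which 7 were higher and 16 lower. The block on the array run left 1 call, dpsA, which was not among the 5, and without the 4 upper-run RNAs there was no call. Leaving out the 20 minute RNA gave 240 calls, the -1 or the 0 minute RNA 0, the 10 or the 25 minute RNA 1, the 80 minute RNA 2 and the 15 minute RNA 3.

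Between late and baseline, the cobalamin synthesis list was lower relative to the other features by camera, with an adjusted p of 0.00726, and adjusted p = 0.479 with an estimated correlation. All 3 differences were negative, with 0 past the threshold over all features or adjusted over the list alone. The values were -0.12 ± 0.05 (SE) for cbiG, -0.092 ± 0.05 for cbiT and -0.076 ± 0.05 for cobN, a cobaltochelatase subunit. The chaperone and proteasome list was higher with an adjusted p of 0.00836, with 5 of 6 differences positive, 0 past the threshold and 3 adjusted over the list alone. It had adjusted p = 0.479 with an estimated correlation. Here panB was at 0.11 ± 0.03, psmA at 0.18 ± 0.06, pan1 at 0.094 ± 0.03 and psmB at 0.12 ± 0.05. The arginine and DMSO list was lower, with 3 of 3 differences negative and an adjusted p of 0.0203, and adjusted p = 0.479 with an estimated correlation. None of its members passed over all features or adjusted over the list alone, and arcA was at -0.069, arcC at -0.086 and moaA at -0.016. Its adjusted p was 0.0565 without the 320 minute RNA. Blocked on the array run, these lists had adjusted p of 0.000669, 0.0167 and 0.0168, and adjusted p = 0.235, 0.533 and 0.533 with an estimated correlation. All baseline and late RNAs lie in the lower run, so the block could not change these differences and altered only their spread. With the dye component adjusted these 3 lists had adjusted p of 0.0557, 0.000213 and 0.242. With the FeSO4 RNA in Alexa 532 alone, camera gave them adjusted p of 0.0734, 0.362 and 0.278. In Alexa 647 alone it gave 0.0915, 0.0905 and 0.0915, so none passed in a single orientation.

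No single feature passed between late and baseline in limma, while 209 of 2688 had an unadjusted p below 0.05 and 134 would be expected by chance. Besides dpsA and the list members above, the values with the smallest p were 0.096 ± 0.04 (SE) for uvrA, an excision repair subunit, -0.061 ± 0.03 for htr6 and -0.068 ± 0.04 for gdhB. The metal transport gene cbiQ was at -0.048 ± 0.04. With the FeSO4 RNA in Alexa 532 alone, 118 features were called, of which 117 were higher.

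Between late and early, 9 named genes fell. They were the ribosomal protein genes rpl12p (-0.35 ± 0.07, SE) and rpmC (-0.31 ± 0.07), the enolase gene eno (-0.24 ± 0.04), the cobalamin synthesis genes cbiT (-0.18 ± 0.04) and cbiG (-0.18 ± 0.04), the cobalt uptake gene cbiQ (-0.13 ± 0.03), guaB (-0.15 ± 0.04), icd, the isocitrate dehydrogenase of the TCA cycle (-0.15 ± 0.04), and ndk, nucleoside diphosphate kinase (-0.14 ± 0.04). Their adjusted p by limma ran from 0.00932 for eno to 0.0432 for icd and ndk, and all 9 had negative differences in both orientations. No named gene rose. In each of the 9 genes the high values lay at 5, 10, 15 and 25 minutes, all on the upper array numbers. For rpl12p they were 0.33, 0.36, 0.30 and 0.25, against -0.09 at 20 minutes. Blocked on the array run, the difference was -0.03 ± 0.06 for rpl12p and for rpmC, -0.12 ± 0.06 for eno, and between -0.067 and -0.0055 for the other 6, and none passed. Within the lower array numbers the 20 minute RNA is the only early one.

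**Figure D3:**
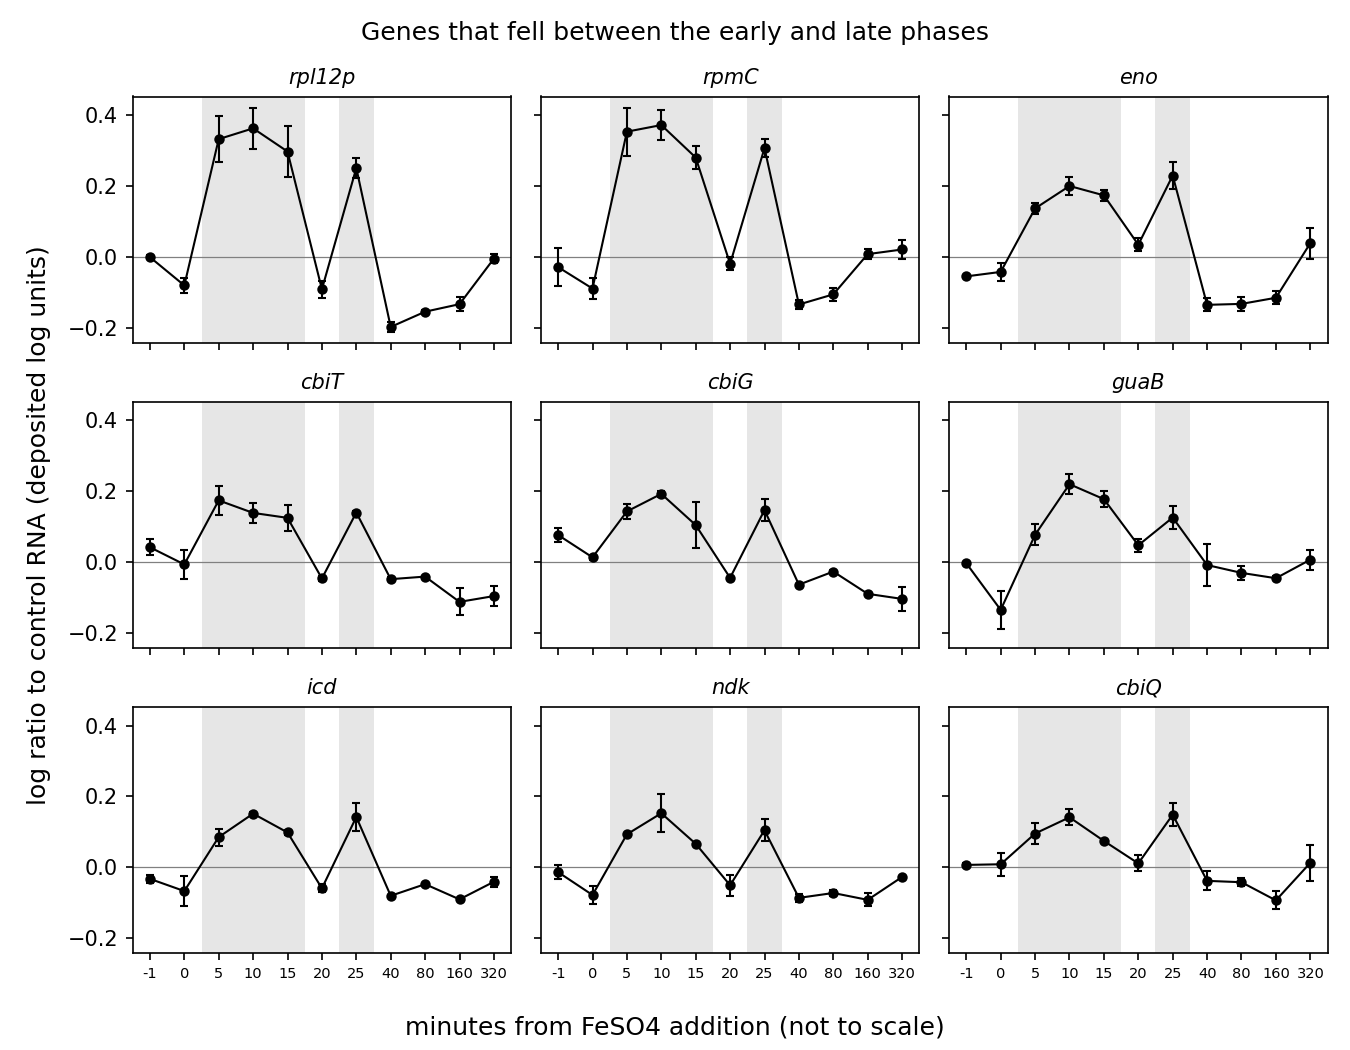
Log ratio to the control RNA (vertical axes, deposited log units) of the 9 named genes that fell from early to late, at each time (horizontal axes, minutes, not to scale). Points are means of the 2 arrays of an RNA, bars are the deviation of the 2 printed copies from their mean, and grey marks the RNAs of the upper array numbers, where rpl12p lies between 0.25 and 0.36.

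As groups, the nucleotide synthesis list was lower late than early by camera, with an adjusted p of 0.00836, and adjusted p = 0.479 with an estimated correlation. All 12 differences were negative, 1 gene (guaB) passed over all features, and 1 adjusted over the list alone. Members that did not pass were pyrI (-0.13) and pyrB (-0.082), the aspartate carbamoyltransferase subunits, and purE (-0.046). The TCA cycle list was lower with an adjusted p of 0.0260, and adjusted p = 0.479 with an estimated correlation. Its 6 differences were all negative, with 1 gene (icd) past the threshold over all features and 1 adjusted over the list alone. Of the others, sucD was at -0.097, mdh at -0.068 and citZ at -0.047. The cobalamin list was lower with an adjusted p of 0.0179, and adjusted p = 0.479 with an estimated correlation. In it cbiT and cbiG fell, also adjusted over the list alone, and cobN was at 0.00017. The chemotaxis list was higher with an adjusted p of 0.0405, and adjusted p = 0.579 with an estimated correlation. Of its 11 differences 8 were positive and none passed over all features or adjusted over the list alone. Here cheR was at 0.093, cheY at 0.088, htr18 at 0.094 and htr4 at 0.075, and htr18 and htr4 differed in sign between the orientations. Blocked on the array run, the nucleotide, TCA cycle, cobalamin and chemotaxis lists had adjusted p of 0.839, 0.231, 0.986 and 0.839, and none passed. Relative to the other features all 4 turned direction, while in the cobalamin list 2 of 3 differences stayed negative, at a median of -0.027. With the dye component adjusted, camera lost the nucleotide, TCA cycle and cobalamin calls (adjusted p of 0.0557, 0.262 and 0.129). It kept the chemotaxis call (0.00468). The TCA cycle call was lost without the 5, 40 or 80 minute RNA (adjusted p of 0.139, 0.185 and 0.0529), the cobalamin call without the 40 minute RNA (0.0665) and the chemotaxis call without the 10, 15 or 320 minute RNA (0.144, 0.0965 and 0.147). The dpsA difference was -0.06 ± 0.07 (SE), with an adjusted p of 0.910. Blocked on the array run, it was -0.32 ± 0.08 (SE), with an adjusted p of 0.329.

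In all, 90 of 2688 features were called between late and early, 12 higher and 78 lower. With each array centred on its median 101 were called, 21 higher and 80 lower, and after quantile normalization 32, of which 9 were higher and 23 lower. After scale normalization none was called. With the dye component adjusted 132 were called, 64 higher and 68 lower. With the FeSO4 RNA in Alexa 532 alone 256 were called, 120 higher and 136 lower, and in Alexa 647 alone none was. The block on the array run left 1 call, which was not among the 90. Leaving out 1 RNA gave 337 calls without 20 minutes, 41 without 5, 22 without 10, 33 without 15, 20 without 25, 25 without 40, 27 without 80 and 11 without 160 minutes. In 82 of the 90 features the ratios of 5, 10, 15 and 25 minutes all lay on 1 side of the 20 minute ratio. The 90 were called on these same ratios, and the share over all 2688 features was not counted. This count therefore does not set the called features apart from the rest.

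The slope over the 9 RNAs after the addition was fitted for gradual change with time. The 4 RNAs of the upper array numbers are all early, so a difference between the runs enters the slope as well. Without these 4, the slopes of rpl12p, rpmC, arcC and cheR turned sign, while the other slopes named here kept theirs. No named gene passed in limma, and 25 of 133 had an unadjusted p below 0.05. Among negative slopes, the smallest p were those of cbiT (-0.051 ± 0.01 per doubling of time, SE), cbiG (-0.049 ± 0.01), rpl12p (-0.084 ± 0.03), rpmC (-0.072 ± 0.02) and guaB (-0.034 ± 0.01). Among positive slopes, they were those of cheY (0.027 ± 0.0096), cheR (0.021 ± 0.01), srp19, of the signal recognition particle (0.017 ± 0.0086), arcC (0.020 ± 0.01) and glyA, serine hydroxymethyltransferase (0.016 ± 0.01). The dpsA slope was -0.012 ± 0.02. In all, limma called 1 of 2688 features, the unnamed feature 4099 at 0.045 ± 0.0065 with an adjusted p of 0.0342, and it was named after its value was seen. Without the 4 RNAs of the upper array numbers 63 features were called, 6 rising and 57 falling. Over these 5 RNAs of 20 to 320 minutes the dpsA slope was -0.10, with an adjusted p of 0.00254, and the glyA slope 0.047, with an adjusted p of 0.0492. The other slopes named here did not pass, at -0.016 for cbiT, -0.015 for cbiG, 0.024 for rpl12p, 0.022 for rpmC, -0.012 for guaB, 0.0045 for cheY, -0.0034 for cheR, 0.0053 for srp19 and -0.024 for arcC. Leaving out the 20 minute RNA gave 14 calls, and leaving out any 1 of the other 8 RNAs except 40 minutes gave 0.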

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

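All tests of explanations in this part were chosen after the results they bear on had been seen.

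Among 90 groups of early or late values of named genes, 7 held a value far from the rest, where chance gives about 4.5. In 5 of them it was the 20 minute RNA among the early ones. Its ratio was -0.020 for rpmC against 0.281 to 0.373 at the other early times, -0.092 for rpl12p against 0.251 to 0.363, -0.17 for thiD against 0.142 to 0.192, -0.047 for cbiT against 0.124 to 0.174, and -0.13 for pyrB against 0.0051 to 0.041. The others were eno at 320 minutes, 0.039 against -0.136 to -0.116 at the other late times, and msrA, a methionine sulfoxide reductase, at 160 minutes, -0.054 against 0.067 to 0.087. A tested difference between late and early stood out for rpl12p (-0.35), rpmC (-0.31), eno (-0.24), cbiT (-0.18), cbiG (-0.18), guaB (-0.15), icd (-0.15), ndk (-0.14) and cbiQ (-0.13).

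The 5, 10, 15 and 25 minute RNAs stood apart from the 20 minute RNA and the rest. Exposure time alone is argued against, since the 4 pairs of neighbouring times that cross between the sets correlated at 0.0973 at most, against at least 0.589 among the 4 RNAs. The array run was not tested apart from the pattern itself, since the 20 minute RNA is the only early one in the other run and its correlation, on average 0.512 higher with the RNAs of 40 to 320 minutes than with these 4, restates the pattern. A wrong label of the 20 minute RNA stays open, since its highest correlation with a baseline or late RNA, 0.742, was not above every other pair. The array run, which may stand for the hybridisation, the RNA preparation or a separate culture, stays open. An early response shared by the 4 RNAs cannot be told apart from the run, since the 20 minute RNA is the only early one in the other run.

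The dpsA ratio was higher at 20 minutes than at -1 and 0 minutes. A difference between the upper and lower stretch of array numbers is argued against, since these RNAs lie in 1 run. They differed by 0.542, with a baseline SD of 0.0219 that rests on -1 and 0 minutes alone. A batch within the lower stretch was not tested. Of the baseline arrays, only the Alexa 647 array of 0 minutes (number 7107) lies on the 20 minute side of its widest gap. The dpsA ratio there was 0.10, against 0.59 at 20 minutes in Alexa 647. A dye effect of 1 orientation is argued against, since the smaller difference of the 2 orientations was 0.538, and so is a defect of 1 printed copy, with a smaller difference of 0.532. This may reflect a transient rise of dpsA RNA after iron addition, as a hypothesis from 1 RNA. No time course without FeSO4 was analysed here, so handling or time in culture was not tested, a wrong label stays open as above, and with ratios left unturned dpsA was at -0.080.

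Of 100 splits of the 9 RNAs after the addition into 5 and 4 (of 126 possible), 4 gave at least the 90 calls of late against early. The real split was 1 of these 4. A count of 4 in 100 excludes chance only if the 9 RNAs are treated as exchangeable. The highest other count was 377, for the split that sets exactly the 5, 10, 15 and 25 minute RNAs against the rest. In the 6 drawn splits that keep these 4 together the counts ran from 1 to 377, and in the other 94 none was above 0. Of the 5 other splits that keep them together 3 gave more calls than the real one. With only 6 such splits, this comparison could not have excluded chance whatever its outcome, so nothing is concluded from it. Over all the splits drawn, calls appeared only where the 5, 10, 15 and 25 minute RNAs stayed together. The array run and a shared early response would both give this.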

How the results depend on the processing

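The alternatives run on exact 0, turning, the array run and the dye component were chosen after seeing the data, as was the narrowing of the named genes. Over the alternatives, the values of named genes kept direction and side of the threshold 1807 times, passed it newly 54 times, lost it 148 times and turned sign 94 times. All 148 losses fell on the 9 genes called late against early, the only named genes past the threshold in the main fits. The 1807 include values that did not pass in the main fit and still did not pass. Under the whole naming rule, 231 of 3817 values in the phase contrasts turned sign, 147 of them in genes not named here, and 67 of 134 gene and contrast pairs turned at least once, 43 of them not named here. The cause was not tested where no cause is given. Signal over background is not in the values used, so its effect is unknown. Counts of calls below are between early and baseline, late and baseline, late and early, and for the slope, where they differ by over 1.5 times from 5, 0, 90 and 1, and for the 11 list calls.

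With the FeSO4 RNA in Alexa 532 only there were 47, 118, 256 and 179 calls and 2 list calls, dpsA at 20 minutes was 0.43, and early against baseline carA was -0.0075 and purB -0.084, and late against baseline moaA 0.061. With it in Alexa 647 only there were 0 calls in all 4 and 0 list calls, dpsA at 20 minutes was 0.59, arcA was 0.0039 early against baseline, htr18 -0.045, htr4 -0.015, cobN -0.019 and sdhC 0.024 late against early, and the srp19 slope was -0.011. All 22 arrays with a dye term gave 100 (early against baseline), 183 (late against early) and 31 (slope), at a correlation of the 2 arrays of an RNA of -0.215.

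Centring gave 24 calls early against baseline, dpsA at 20 minutes of 0.47 and late against early cobN of -0.0014. Scale normalization gave 1 (early against baseline), 0 (late against early) and 0 (slope), dpsA of 0.74, arcA of 0.0022 (early against baseline) and sdhC of 0.0031 (late against early). Quantile normalization gave 23, 32 and 0 in the same order, dpsA of 0.42, late against early dpsA of 0.012 and sdhC of 0.0048, and a dpsA slope of 0.0063. Spot medians gave 11 early against baseline and late against early cobN of -0.00021. Without the 25% of features whose orientations differed most, 2016 features were tested, with 10 (early against baseline) and 45 (late against early). Without features with a missing spot, 1304 were tested, with 11 (early against baseline) and 0 (slope). The trended robust prior gave 3 early against baseline.

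The array number as covariate gave 0 calls early against baseline, late against early and for the slope, and 1 list call. Early against baseline, thiD was then -0.018, cbiQ -0.025, moaA 0.012, arcA 0.050, cheA 0.018, cheY 0.15 and purB -0.031, late against baseline moaA was 0.018, late against early citZ was 0.011, and slopes were -0.011 for arcC, 0.015 for rpl12p and 0.0060 for rpmC. A phase border after 40 minutes gave 2 (early against baseline) and 0 (late against early). With 0 minutes counted as early there were 0 and 0, with late against early cobN of -0.0093 and sdhC of 0.018, and the lone baseline RNA was assumed to vary like the others. Unlogged minutes gave a slope count of 0. Turning every sign gave dpsA of -0.51 at 20 minutes.

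Exact 0 kept gave early against baseline purB of -0.0043. Ratios left unturned gave 0 (early against baseline), 0 (late against early) and 10 (slope), with dpsA of -0.080 at 20 minutes. The array run as a block gave 1, 1 and 1 calls in the phase contrasts and 5 list calls, 3 of them shared. The other 2 were the cobalamin list, lower early against baseline (adjusted p 0.0167), and the arginine and DMSO list, lower late against early (0.0315), and with an estimated correlation 0 were called. Without the 4 RNAs of the upper run there were 0 (early against baseline), 0 (late against early), 63 (slope) and the same 5 list calls, 3 of them shared. In both, early against baseline thiD was -0.0012, moaA 0.050, arcA 0.044 and cheY 0.075, and late against early sucD was 0.077, mdh 0.064, citZ 0.069, cheR -0.0010, cheY -0.025, htr18 -0.026, htr4 -0.0027, pyrI 0.041, pyrB 0.038, msrA -0.022, sdhC 0.032 and phoU 0.088. The dpsA slope without the 4 RNAs was -0.10 and the glyA slope 0.047, both newly past the threshold, and dpsA early against baseline passed with the block (adjusted p 0.0467) and not without the 4 RNAs (0.0710). Other slopes without the 4 RNAs were -0.0034 for cheR, -0.024 for arcC, 0.024 for rpl12p and 0.022 for rpmC. The 3 shared list calls were those of late against baseline in both fits. Neither fit can change those differences, since all baseline and late RNAs lie in the lower run.

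The dye component adjusted gave 68 (early against baseline), 16 (slope) and 4 list calls, dpsA at 20 minutes of 0.55, and late against early dpsA of 0.0066 and sdhC of 0.0055. Its 132 calls late against early, 64 higher and 68 lower, shared 73 with the 90. Adjusted and blocked on the run there were 21, 9 and 7 calls in the phase contrasts and 1 list call, with dpsA of 0.55. Early against baseline moaA was then 0.022, arcA 0.059, cheY 0.065 and purB -0.020, and late against early icd was 0.00016, sucD 0.084, mdh 0.073, citZ 0.078, cheY -0.016, htr18 -0.012, pyrI 0.048, pyrB 0.045, msrA -0.012, sdhC 0.042 and phoU 0.098. An estimated correlation and fry each gave 0 list calls.

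Leaving out each RNA in turn gave 0 to 240 calls early against baseline, 0 to 1 late against baseline, 11 to 337 late against early, 0 to 14 for the slope and 9 to 12 list calls. Early against baseline, arcA ran from -0.034 to 0.0044 and cheY from -0.10 to 0.029. Late against early, dpsA ran from -0.11 to 0.0025, cobN from -0.031 to 0.023 and sdhC from -0.027 to 0.0038. The dpsA slope ran from -0.043 to 0.013.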

Other observations

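Gene groups outside the calls showed small differences. Between late and early, 6 of 12 aminoacyl-tRNA synthetase genes had positive differences, with 0 past the threshold over all features, 1 adjusted over the list alone and an adjusted p by camera of 0.872. The list of bacteriorhodopsin and retinal proteins (the opsin genes hop, sop1 and sop2 and the regulator bat) had 3 of 4 negative differences, and the adjusted p was 0.872. Of 8 genes of DNA repair and replication, 6 had positive differences with 1 past the threshold adjusted over the list alone, and the adjusted p was 0.925. Since camera compares a list with the other features, its direction opposed the sign of the median for some lists without a call. It was lower between early and baseline for the aminoacyl-tRNA synthetase (median 0.017), retinal (0.023) and cobalamin (0.064) lists, of which the cobalamin list was called lower with the array run as a block. Between late and baseline it was lower for the aminoacyl-tRNA synthetase (0.0038), TCA cycle (0.0055), retinal (0.011) and nucleotide (0.018) lists, and the chemotaxis list had a mean of 0.013 beside a median of -0.016. Between late and early it was lower for the aminoacyl-tRNA synthetase list (median 0.00018, mean -0.010), and higher for the DNA repair list, with a mean of -0.0051 beside a median of 0.019.

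Lists of 1 or 2 named genes gave values only. Between late and early, nuoL, a subunit of the respiratory NADH dehydrogenase family, was at -0.11 ± 0.03 (SE) with an adjusted p of 0.0617 by limma, and sdhC, of succinate dehydrogenase, at -0.015 ± 0.04. The ferredoxin gene fer2 was at -0.091 ± 0.04, msrA at 0.043 ± 0.03 and phoU, a regulator of phosphate uptake, at -0.12 ± 0.05. None of them passed. The ribosomal protein list held rpl12p alone, since the symbol rpmC did not match its pattern.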
